A study of Homo sapiens with 6 samples.

How the data were processed

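Total RNA of VCaP cells, a prostate cancer cell line that carries the TMPRSS2/ERG fusion, was profiled on Affymetrix Human Genome U133 Plus 2.0 arrays. Per the labels' protocols, cells were transfected with 1 of 2 independent SOX9 siRNAs, here siRNA A and siRNA B, or with a non-targeting control siRNA, and RNA was collected 72 h later. Biotin-labelled cRNA was prepared from 6 ug of total RNA per sample. Each of the 3 groups held 2 arrays, 6 in all, which the design text calls biological duplicates.

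The deposited values are array intensity on a linear scale, 1 signal per probe set, and the submitters' processing notes name MAS5. Its version and scaling target are not given in the sources used here. The deposited table held 54675 probe sets. The 2%-trimmed mean signal was 165 and 160 in the siRNA A arrays, 144 and 190 in the siRNA B arrays and 157 and 176 in the control arrays. The highest was 1.32 times the lowest, so the arrays as deposited did not share 1 trimmed mean. Whether they were scaled to 1 target in another way is not known. The median signal was 22.9 and 22.6 with siRNA A, 21.2 and 26.3 with siRNA B and 23.0 and 25.8 with control siRNA. The GAPDH 3'/5' signal ratio ran from 1.04 to 1.19 and the ACTB ratio from 2.91 to 3.79. The number of arrays limits the precision of every value.

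Signals were used as log2(signal + 16), with the authors' scaling between arrays kept. A fold change is on this scale and understates the change of dim genes. The 62 control probe sets were left out. In the annotation table given, 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. For 41043 of the first kind the gene identifier was found in the RefSeq gene table of GRCh38.p14, which left 0 symbols to update. A gene was represented by its probe set with the highest mean among those of that gene alone. Genes with a mean below the median of all probe sets, 5.25 on the log2 scale or a signal of 22.0, were left out. This left 12431 genes tested and 7344 not tested. Genes with no probe set of their own in that table were not analysed here.

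Genes were tested with limma 3.58.1 in R 4.3.3, with lmFit on the 3 groups over all 6 arrays, which leaves 3 residual degrees of freedom, and eBayes with an intensity trend. The contrasts were the mean of both siRNAs against control, each siRNA against control, and siRNA A against siRNA B. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. In data simulated for both siRNAs against control, with 12431 independent genes and 200 changed genes in each of 5 runs, the test called 57.0% of genes changed 2-fold, 99.7% of those changed 4-fold, 7.46% of those changed 1.5-fold and 0.0670% of unchanged genes. Over the 5 runs these were 191, 329 and 25 changed genes and 41 unchanged ones. The simulation gave every array the same spread and no deviation shared by same-numbered arrays, so its shares may not hold for these data.

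The 33 gene lists were fixed before the data were examined, as were the design, the settings to vary and the rule for named genes. Of their 982 symbols, 980 matched a gene and 888 had a probe set of their own. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. A shift is the mean log2 fold change of a list minus that of the other tested genes. Camera with an estimated correlation and limma's fry were run beside it. Named genes were SOX9, up to 12 called genes per direction for both siRNAs, up to 5 for each siRNA and up to 8 for siRNA A against siRNA B, each with all arrays on 1 side of the other group. Lists with fewer than 5 such genes were filled to 5 by unadjusted p, as values only. Up to 4 members per gene list with the smallest p for both siRNAs were also open to naming.

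The replicate numbers are the same in all groups, and nothing in the labels says that a number marks a shared culture or day. The deviations of same-numbered arrays from their group means correlated at 0.63 between siRNA A and siRNA B and at 0.18 between each siRNA and control, each over 0.1, so the numbers were taken to pair the arrays. The choice was made from the data and after the calls of the fit with the replicate block had been seen. The fit without the block, fixed before the data were examined, stayed the first one, and blocked values stand beside the results they change. The block takes the change between replicates as equal in all groups, which the lower correlation with control does not bear out. Its spread came from limma's trend alone, so blocked p-values can be too small.

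The alternatives were other log offsets, quantile normalization, median centring, no filter and a stricter filter, the median over a gene's probe sets, probe sets in place of genes, other eBayes settings, only the compared groups in the fit, the replicate number as a block, the siRNA arrays as 1 group, each array left out in turn, and other thresholds. A common trimmed mean, the block together with median centring, and fits without either replicate of both SOX9 siRNAs were added after the data had been seen. These last fits took the arrays left of both siRNAs as 1 group.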

Results

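The data were 6 arrays of VCaP cells, 2 each with SOX9 siRNA A, SOX9 siRNA B and control siRNA, collected 72 h after transfection. The series title places the experiment in a study of SOX9, a transcription factor of the SOX family, and the WNT pathway in prostate cancer. The design compares SOX9 knockdown with control, and the use of 2 siRNAs allows the effects of each to be compared. Over the tested genes, the correlation between arrays was 0.988 within the control group, 0.973 within siRNA A and 0.965 within siRNA B. Replicate 1 of siRNA A correlated with control replicate 2 at 0.988. The first principal component held 54.0% of the variance.

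SOX9 itself had the lowest signal with siRNA B and an intermediate signal with siRNA A. For the probe set that represented the gene, the signal was 1298 ± 243 with control siRNA, 890 ± 308 with siRNA A and 471 ± 195 with siRNA B (SD, n = 2 each). For the other SOX9 probe set it was 1414 ± 204, 723 ± 194 and 431 ± 196. In both probe sets all 4 SOX9 siRNA arrays lay below both control arrays. Within each siRNA the replicate 2 array had the lower SOX9 signal, 673 against 1108 for siRNA A and 334 against 609 for siRNA B in the first probe set. The log2 fold change of SOX9 for both siRNAs was -1.02 (SE 0.29), or 49.2% of the control level, and did not pass the test (limma adjusted p = 0.425). With the replicate number as a block it was also -1.02 and passed (limma adjusted p = 0.00184). It was -0.57 for siRNA A (limma adjusted p = 0.999) and -1.48 for siRNA B (limma adjusted p = 0.111). In a fit over all probe sets, the other SOX9 probe set was at -1.36 for both siRNAs (limma adjusted p = 0.328), or 39.1% of control, and the first at -1.02 (limma adjusted p = 0.571). The difference between the siRNAs, 0.91, did not pass either (limma adjusted p = 0.428). After quantile normalization, median centring or scaling to a common trimmed mean, the first probe set had replicate 1 of siRNA A above control replicate 2 (10.13 against 10.09 on the log2 scale after quantile normalization).

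**Figure D1:**
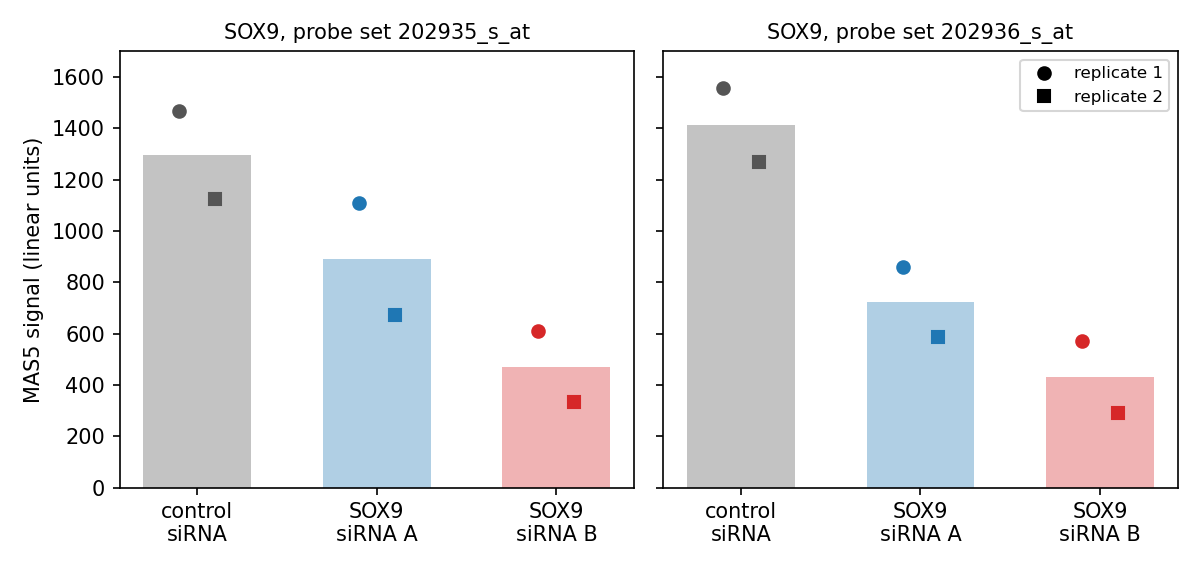
MAS5 signal of SOX9 (linear units, vertical axis) for the 2 probe sets of the gene, by group. Bars are group means, circles are replicate 1 and squares replicate 2; in the probe set that represented the gene the control mean was 1298, that of siRNA A 890 and that of siRNA B 471.

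With both siRNAs against control, HMGN2P46, SLC30A4 and COXFA4L3 rose, and NPY6R and FZD7 fell. FZD7, a Frizzled receptor for WNT ligands, had a signal of 182 ± 28.0 with control, 54.8 ± 28.4 with siRNA A and 30.6 ± 15.5 with siRNA B (SD, n = 2 each). SLC30A4, a zinc transporter, rose from 1726 ± 470 to 4880.5 ± 1238 with siRNA A and 6283 ± 2258 with siRNA B. The transcribed pseudogene HMGN2P46 went from 51.8 ± 9.55 to 334 ± 66.2 and 180 ± 3.39, and NPY6R, a neuropeptide Y receptor pseudogene in humans, from 833 ± 25.0 to 215 ± 104 and 141 ± 88.4. The probe set of HMGN2P46 is of a type that can hybridise to related transcripts, so its source is uncertain.

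The log2 fold changes of the genes that rose were 1.95 for HMGN2P46 (SE 0.24, limma adjusted p = 0.00497), 1.66 for SLC30A4 (SE 0.24, limma adjusted p = 0.0186) and 1.501 for COXFA4L3 (SE 0.24, limma adjusted p = 0.0339). Those of the genes that fell were -2.26 for NPY6R (SE 0.33, limma adjusted p = 0.0186) and -1.83 for FZD7 (SE 0.29, limma adjusted p = 0.0325). Each of the 5 lay on 1 side of both control arrays in 4 of 4 SOX9 siRNA arrays. The nearest genes past these did not pass the test: MMP10, a matrix metalloproteinase, had a log2 fold change of 1.46, UGT2B28 of 1.29, TESC of -1.71, SLC24A2 of -1.52 and ART3 of -1.51, with limma adjusted p from 0.0663 to 0.0785. In all, 5 of 12431 genes were called, 3 higher and 2 lower, and 965 had an unadjusted p below 0.05 where chance gives 622.

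The count of 5 was 0 after quantile normalization, median centring, scaling to a common trimmed mean, without the filter on dim probe sets and with the siRNA arrays as 1 group, in limma with 1117, 1058, 1086, 1225 and 739 genes at an unadjusted p below 0.05. It was 14 without replicate 1 and 0 without replicate 2 of siRNA A, 62 without replicate 1 and 0 without replicate 2 of siRNA B, and 22 and 32 without control replicates 1 and 2. Without replicate 2 of both SOX9 siRNAs it was 0 in limma, with 552 genes at an unadjusted p below 0.05, and without replicate 1 of both it was 602, with 215 higher and 387 lower. These fits took the arrays left of both siRNAs as 1 group, so they compare with the 0 of that fit on all arrays. Deviations shared by same-numbered arrays then count as effect. With the replicate block the count was 440 (60 with median centring added), the 440 including all 5, MMP10, UGT2B28, TESC, SLC24A2 and ART3. With that block limma took the spread of every gene from its trend alone. None of the 5 was called without replicate 2 of either siRNA. COXFA4L3 was also not called without replicate 1 of siRNA A (1.39) or without control replicate 1 (1.55) or 2 (1.45). The log2 fold changes moved less. FZD7 ran from -2.21 to -1.22 over the 20 alternatives that tested it and was called in 9. SLC30A4 ran from 1.35 to 2.16 over 21 alternatives and was called in 11.

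**Figure D2:**
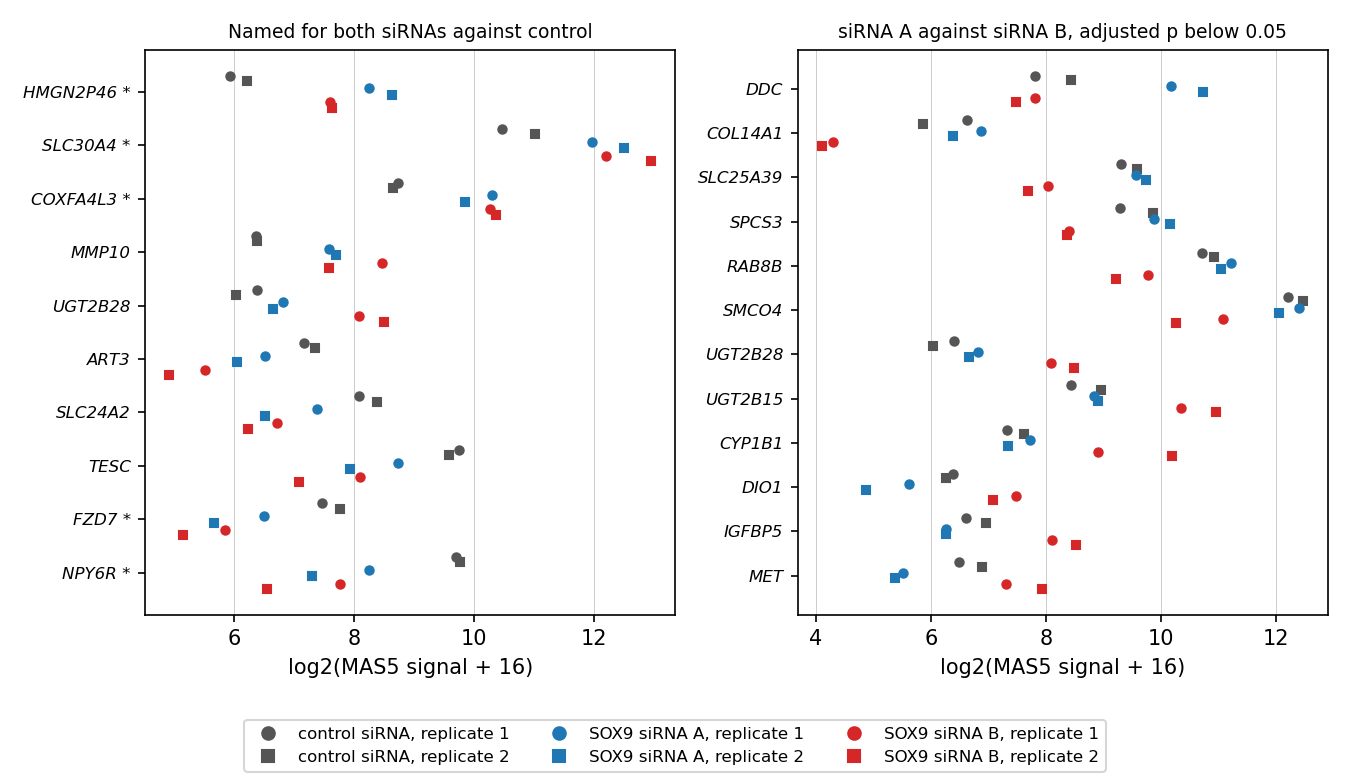
Expression per array as log2(MAS5 signal + 16) (horizontal axis) of the genes named for both siRNAs against control (left; an asterisk marks the 5 called genes) and of the 12 genes called between siRNA A and siRNA B (right). Circles are replicate 1 and squares replicate 2; all 4 SOX9 siRNA arrays of FZD7 and NPY6R lie below both controls.

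Genes of the WNT pathway were examined in 4 lists. The beta-catenin/TCF target genes were lower with both siRNAs: 20 of 26 had a negative log2 fold change, and the list shifted by -0.26 (camera adjusted p = 0.00386; adjusted p = 0.919 with an estimated correlation). NRCAM, a cell adhesion gene, had a log2 fold change of -1.14 (SE 0.28) and was the 1 member called when adjusted over the list alone; over all genes tested, 0 were called. MYC had -0.78 and PPARD -0.63, while BAMBI, an inhibitor of TGF-beta receptors, had 0.76; none of these passed. With the replicate block NRCAM, MYC, BAMBI and WNT5A passed, with limma adjusted p of 0.000348, 0.000804, 0.0373 and 0.00302, as did DKK3 (0.00579) and TCF7L2 (0.0320). Of 19 WNT ligands and receptors, FZD7 was the 1 called over all genes and over the list alone, WNT5A had 0.97 (1.36 without replicate 1 of siRNA B, limma adjusted p = 0.0475) and WNT2 -0.65, and the list shift of -0.12 did not pass (camera adjusted p = 0.358).

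The WNT antagonists and destruction complex genes shifted by -0.16 (27 genes, camera adjusted p = 0.0654), with DKK3 at -1.12, a value of uncertain size since its signal with the siRNAs, 16.5 ± 14.9 and 15.2 ± 17.9 (SD, n = 2 each), was below the filter level of 22.0, and SOSTDC1 at -0.68, and WNT signal transduction genes by -0.02 (25 genes, camera adjusted p = 0.956), with TCF7L2 at -0.81; 0 members of either were called, over all genes or adjusted over the list alone. The level of the beta-catenin/TCF targets relative to the control mean was -0.15 and -0.36 in replicates 1 and 2 of siRNA A and -0.10 and -0.45 in those of siRNA B. Without replicate 2 of both SOX9 siRNAs the list's shift was -0.12 (camera adjusted p = 0.0866), and without the filter on dim probe sets -0.16 (camera adjusted p = 0.0954).

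Genes of cholesterol and fatty acid synthesis were higher with both siRNAs, and those of hypoxia and glycolysis and of NF-kappaB and inflammation were lower. Of 25 cholesterol and fatty acid genes, 24 had a positive log2 fold change, and the list shifted by 0.67 (camera adjusted p = 2.19e-13; adjusted p = 0.919 with an estimated correlation). STARD4, a sterol transport protein, had 1.40, HMGCS1, which makes HMG-CoA, 1.15, IDI1 1.03 and MSMO1 0.95. The NF-kappaB list shifted by -0.74 (18 genes, 15 negative, camera adjusted p = 4.03e-05; adjusted p = 0.919 with an estimated correlation), with the chemokine genes CCL2 at -2.77 (SE 1.07), CXCL1 at -1.28 and CXCL3 at -1.25. The hypoxia and glycolysis list shifted by -0.43 (31 genes, 26 negative, camera adjusted p = 4.03e-05; adjusted p = 0.919 with an estimated correlation), with CA12, a carbonic anhydrase, at -1.57 and EGLN3, a prolyl hydroxylase, at -1.07. In these 3 lists 0 members were called over all genes, and 0 adjusted over the list alone. The estimated inter-gene correlation was 0.81 for cholesterol, 0.65 for hypoxia and 0.64 for NF-kappaB genes, against the preset 0.01. Over the 8 lists that passed for both siRNAs it ran from 0.099 to 0.81. The preset takes members as nearly independent, so camera p-values at the preset can be far too small. With the replicate block all of the members named here were called, the largest limma adjusted p among them being that of EGLN3, 0.000817. For hypoxia, NF-kappaB and cholesterol genes, replicate 2 minus replicate 1 was -0.98, -1.28 and 0.87 in the SOX9 siRNAs. In control it was -0.25, -0.034 and -0.026. The block takes this change as common to all groups. Its spread came from limma's trend alone, so these calls understate the spread of such genes.

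Replicate 2 of both SOX9 siRNAs stood apart from the other arrays in these 3 lists. Relative to the control mean, the hypoxia list was at 0.02 and -0.88 in replicates 1 and 2 of siRNA A and at 0.11 and -0.95 in those of siRNA B, with controls at 0.12 and -0.12. The NF-kappaB list was at 0.07, -1.49, -0.27 and -1.26 in the same order, and the cholesterol list at 0.02, 0.82, 0.45 and 1.38. Without replicate 2 of both SOX9 siRNAs, the hypoxia list shifted by 0.06 (camera adjusted p = 0.644) and the NF-kappaB list by -0.10 (camera adjusted p = 0.362), while the cholesterol list shifted by 0.24 (camera adjusted p = 1.99e-05; adjusted p = 0.953 with an estimated correlation). Single arrays moved these values too: the hypoxia shift was -0.20 without replicate 2 of siRNA A, -0.16 without replicate 2 of siRNA B (camera adjusted p = 0.270), -0.65 and -0.69 without their replicates 1. The NF-kappaB shift was -0.35 and -0.49 without the replicate 2 arrays of siRNA A and siRNA B and -1.13 without replicate 1 of siRNA A. The cholesterol shift was 0.44 without replicate 2 of siRNA B.

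Unfolded protein response genes were also higher, by 0.24 (24 genes, 18 positive, camera adjusted p = 0.00152; adjusted p = 0.919 with an estimated correlation), with the endoplasmic reticulum genes MANF at 0.65, HYOU1 at 0.66 and HSPA5 at 0.37, and ATF4 at -0.37. Cytosolic ribosomal protein genes were lower, all 34 with a negative log2 fold change and a shift of -0.11 (camera adjusted p = 4.03e-05; adjusted p = 0.919 with an estimated correlation). NOTCH signalling genes shifted by -0.20 (21 genes, camera adjusted p = 0.0369; adjusted p = 0.919 with an estimated correlation), with MAML2, a NOTCH coactivator, at -0.88 and the ligand JAG1 at 0.53. DNA replication and G1/S genes shifted by -0.14 (45 genes, camera adjusted p = 0.0369; adjusted p = 0.963 with an estimated correlation), with CDT1 at -0.76 and CCNE1, cyclin E1, at -0.57. In these 4 lists 0 members were called, over all genes or adjusted over the list alone, while MAML2 and CDT1 passed with the replicate block (limma adjusted p = 0.00836 and 0.0373). The unfolded protein response shift was 0.11 without control replicate 1 (camera adjusted p = 0.363) and 0.37 without control replicate 2. The DNA replication shift was 0.03 without control replicate 2 (camera adjusted p = 0.876), -0.31 without control replicate 1 and -0.15 without replicate 1 of siRNA A (camera adjusted p = 0.0776), and the list lost its call with the replicate block (camera adjusted p = 0.0546). NOTCH genes lost their call without replicate 2 of siRNA A (-0.12), replicate 2 of siRNA B (-0.10) or control replicate 1 (-0.17), and the ribosomal shift was -0.02 without replicate 2 of siRNA B and -0.21 without replicate 1 of siRNA B.

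**Figure D3:**
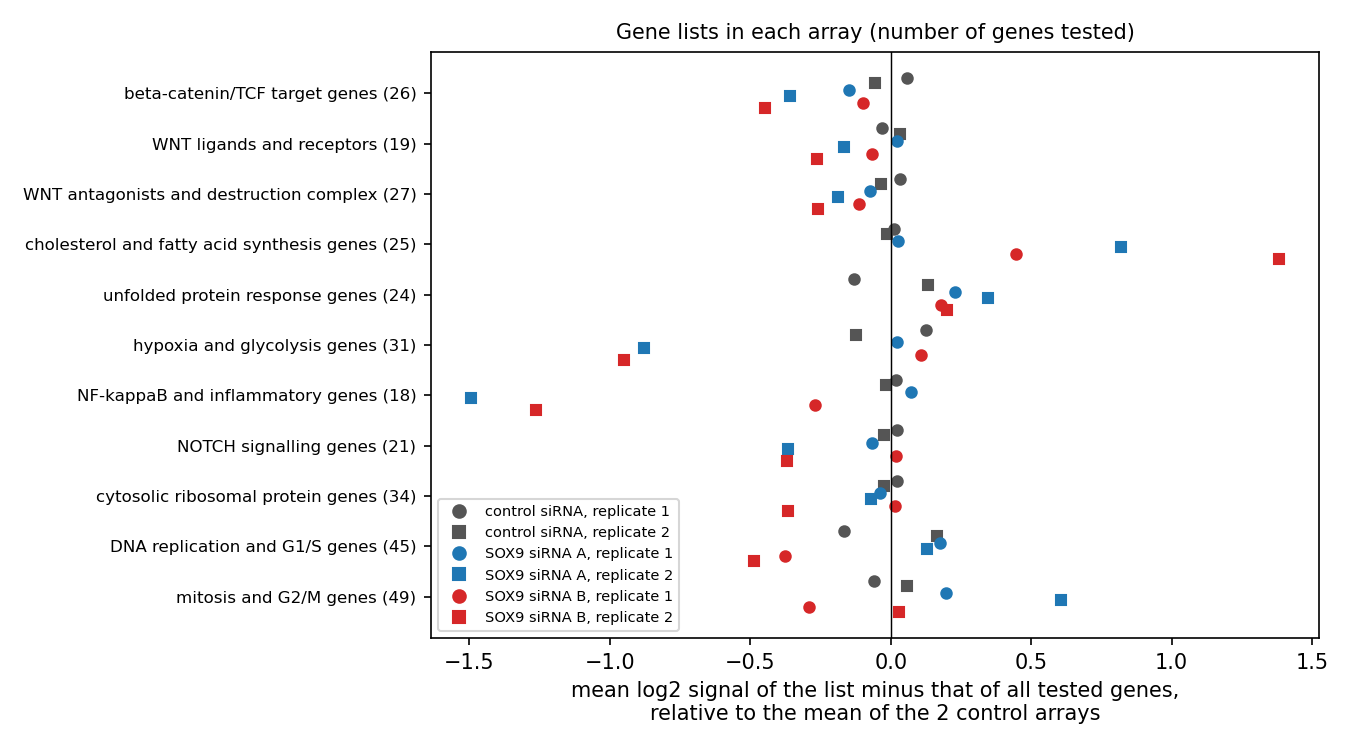
Mean log2 signal of 11 gene lists minus that of all tested genes, relative to the mean of the 2 control arrays (horizontal axis), in each of the 6 arrays; the number of tested genes follows each name. Circles are replicate 1 and squares replicate 2; for hypoxia and glycolysis genes the replicate 2 arrays of the SOX9 siRNAs lie at -0.88 and -0.95.

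Androgen-related genes and lineage markers showed no list past the test for both siRNAs. Androgen receptor activated genes shifted by 0.03, with HOMER2 at -1.30, called when adjusted over the list alone, SLC45A3 (prostein) at 1.09 and STEAP2 at 0.60. Androgen receptor repressed genes shifted by 0.25 and androgen and steroid metabolism genes by 0.32; the glucuronosyltransferases UGT2B17 (1.44) and UGT2B15 (1.07), which inactivate androgens and stand in both lists, were called when adjusted over either list alone, as were SI (1.68) and DDC (0.93) over the first. The siRNAs differed in DDC, at 2.34 with siRNA A and -0.48 with siRNA B, and in UGT2B15, at 0.18 and 1.96. Both lists passed with the replicate block (camera adjusted p = 0.0209 and 0.0117; adjusted p = 0.944 with an estimated correlation), and HOMER2, SLC45A3, STEAP2, UGT2B17, UGT2B15, SI, DDC and LUM passed too, the largest limma adjusted p being 0.0477. Shifts were -0.04 for luminal epithelial, -0.22 for basal epithelial and prostate stem cell, 0.04 for neuroendocrine, 0.18 for fibroblast and stromal (with lumican, LUM, at 1.47 and called when adjusted over the list alone) and 0.27 for leukocyte and erythroid markers, and -0.08 for mesenchymal and EMT genes. Camera adjusted p ran from 0.0856 to 0.944 over these 9 lists. Only 4 fibroblast and stromal and 2 leukocyte and erythroid markers were tested. The 2 were HBB and CD79A, with group mean signals from 28.7 to 50.1, not far above the filter level of 22.0. ETS transcription factors shifted by -0.14, the SOX family by -0.28 and cartilage genes bound by SOX9 in chondrocytes by -0.05, with camera adjusted p of 0.122, 0.0654 and 0.876. Steroid metabolism genes passed without control replicate 1 (0.30) or 2 (0.33), and androgen receptor repressed genes (0.28) and the SOX family (-0.41) without control replicate 2, with adjusted p from 0.941 to 0.966 with an estimated correlation.

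Among stress and growth lists, the shift was 0.14 for mitosis and G2/M genes, -0.01 for p53 targets, -0.03 for apoptosis regulators, -0.10 for interferon-stimulated genes, 0.13 for the small RNA silencing machinery, -0.04 for heat shock genes and 0.00 for oxidative phosphorylation genes. It was 0.06 for TGF-beta and BMP, 0.16 for Hedgehog and -0.12 for FGF, EGF and IGF signalling genes. None of these passed, with camera adjusted p from 0.0741 to 0.823. Mitosis genes passed without replicate 1 of siRNA A (0.24), replicate 1 of siRNA B (0.22) or control replicate 2 (0.20), and oxidative phosphorylation genes without replicate 2 of siRNA B (-0.052), with adjusted p from 0.915 to 0.966 with an estimated correlation. The mean, the median and the test of a list differed in sign for androgen receptor activated and repressed genes, steroid metabolism, neuroendocrine and fibroblast markers, p53 targets, TGF-beta and BMP and Hedgehog genes. In all, 8 of 33 lists passed for both siRNAs, 2 higher and 6 lower, and 3 passed without replicate 2 of both SOX9 siRNAs. With an estimated correlation 0 lists passed in any of the comparisons (smallest camera adjusted p = 0.919 for both siRNAs), with fry 0, and at an unadjusted p below 0.05 0 by camera with an estimated correlation and 1 by fry for both siRNAs.

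With siRNA A alone, HMGN2P46 and DDC rose. DDC, the decarboxylase that makes dopamine and serotonin, had a signal of 1417 ± 393 against 270 ± 87.5 in control (SD, n = 2 each), a log2 fold change of 2.34 (limma adjusted p = 0.0106), and HMGN2P46 had 2.36 (limma adjusted p = 0.00266). SLC30A4 (1.49), COXFA4L3 (1.38) and NPY, neuropeptide Y (1.80), did not pass, nor did NPY6R (-1.96), PTH2R (-1.80), IGSF3 (-1.48), DNAH6 (-1.32) and TSPAN8 (-1.07). The replicate block gave 224 genes, these 8 among them, and 23 genes with median centring added. PTH2R was at a signal of 19.4 ± 16.97 with siRNA A (SD, n = 2), below the filter level of 22.0, so the size of its value is uncertain. In all, 2 of 12431 genes were called, both higher, with 587 genes at an unadjusted p below 0.05 where chance gives 622. The count was 6 and 0 without replicates 1 and 2 of siRNA A and 7 and 18 without control replicates 1 and 2, and 0 after quantile normalization, median centring or scaling to a common trimmed mean or without the filter, in limma with 672, 631, 636 and 898 genes at an unadjusted p below 0.05.

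Mitosis and G2/M genes were higher with siRNA A, 46 of 49 with a positive log2 fold change and a shift of 0.40 (camera adjusted p = 3.83e-12; adjusted p = 0.843 with an estimated correlation), and DNA replication genes shifted by 0.15 (camera adjusted p = 0.0113; adjusted p = 0.843 with an estimated correlation). Cholesterol genes shifted by 0.42, unfolded protein response genes by 0.29, NF-kappaB genes by -0.71, hypoxia genes by -0.43, beta-catenin/TCF targets by -0.25, NOTCH genes by -0.22, FGF, EGF and IGF genes by -0.20 and ribosomal genes by -0.05, with camera adjusted p from 1.19e-05 to 0.0172 and adjusted p = 0.843 with an estimated correlation for each. In these 10 lists 0 members were called over all genes, and 2 beta-catenin/TCF targets, both lower, when adjusted over the list alone. Of the lower lists none passed without replicate 2 of siRNA A: hypoxia genes were then at 0.022, NF-kappaB genes at 0.071, beta-catenin/TCF targets at -0.15, NOTCH genes at -0.067, FGF, EGF and IGF genes at -0.082 and ribosomal genes at -0.040, and cholesterol genes, at 0.025, did not pass either. The 3 lists that passed without it were higher, mitosis genes among them at 0.20 (camera adjusted p = 0.000689; adjusted p = 0.947 with an estimated correlation).

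Without replicate 1 of siRNA A, hypoxia genes were at -0.88, NF-kappaB genes at -1.49, cholesterol genes at 0.82, mitosis genes at 0.61, NOTCH genes at -0.37 and FGF, EGF and IGF genes at -0.32, interferon-stimulated genes passed (-0.32) and DNA replication genes did not (0.13). Without control replicate 1, DNA replication (-0.013), unfolded protein response (0.16), NOTCH (-0.19) and ribosomal genes (-0.031) lost their calls. Interferon-stimulated genes (-0.19) and leukocyte and erythroid markers (0.62, only 2 genes tested) passed there. Without control replicate 2, DNA replication genes were at 0.32, ribosomal genes (-0.078) lost their call and the SOX family passed (-0.35). Ribosomal genes lost their call with the replicate block, and androgen receptor activated genes (0.15) and interferon-stimulated genes (-0.17) passed. At an estimated correlation none of these lists passed in any of these fits (smallest camera adjusted p = 0.689).

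With siRNA B alone, sucrase-isomaltase (SI), several glucuronosyltransferase genes and CYP1B1, a cytochrome P450, rose. SI went from 349 ± 108 in control to 2298.5 ± 1299.8 (SD, n = 2 each), a log2 fold change of 2.57 (limma adjusted p = 0.0123), UGT2B17 had 2.29 (limma adjusted p = 0.0116), CYP1B1 2.08 (limma adjusted p = 0.0254), UGT2B28 2.07 and UGT2B4 2.03 (limma adjusted p = 0.0116 each). The UGT2B genes are close paralogs whose probe sets may share transcripts, so which of them rose is uncertain. NPY6R (-2.56), the ephrin receptor gene EPHA8 (-2.17), FZD7 (-2.12), TESC (-2.08) and the collagen gene COL14A1 (-2.05) fell, with limma adjusted p from 0.0116 to 0.0228. With siRNA B, COL14A1 was at a signal of 2.40 ± 1.70 and EPHA8 at 10.7 ± 10.96 (SD, n = 2 each), below the filter level of 22.0, so the size of these 2 values is uncertain. In all, 23 genes were called, 11 higher and 12 lower, with 1399 at an unadjusted p below 0.05, and 732 with the replicate block (562 with median centring added). The count was 10 and 13 without replicates 1 and 2 of siRNA A, 991 and 0 without replicates 1 and 2 of siRNA B, and 41 and 69 without control replicates 1 and 2. It was 0 after quantile normalization, median centring or scaling to a common trimmed mean or without the filter, in limma with 1833, 1766, 1764 and 1629 genes at an unadjusted p below 0.05.

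Cholesterol genes shifted by 0.92 with siRNA B, all 25 positive and 16 called when adjusted over the list alone (camera adjusted p = 6.01e-15; adjusted p = 0.984 with an estimated correlation). DNA replication genes shifted by -0.43, with 43 of 45 negative (camera adjusted p = 7.69e-09; adjusted p = 0.984 with an estimated correlation). NF-kappaB genes shifted by -0.77, hypoxia genes by -0.42, beta-catenin/TCF targets by -0.27 (2 higher and 4 lower when adjusted over the list alone) and ribosomal genes by -0.17, with camera adjusted p from 1.53e-05 to 0.0382 and adjusted p = 0.984 with an estimated correlation for each. Without replicate 2 of siRNA B, hypoxia genes were at 0.11, NF-kappaB genes at -0.27, beta-catenin/TCF targets at -0.099 and ribosomal genes at 0.017, all without a call, and cholesterol genes at 0.45, while mitosis (-0.29), unfolded protein response (0.18), heat shock (-0.19) and oxidative phosphorylation genes (-0.060) passed. Without replicate 1 of siRNA B these were at -0.95, -1.26, -0.45, -0.37 and 1.38, and NOTCH (-0.37) and oxidative phosphorylation genes (0.16) passed.

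Without control replicate 1, beta-catenin/TCF targets lost their call with siRNA B (-0.22), and androgen receptor repressed genes (0.35), steroid metabolism (0.44) and mitosis genes (-0.19) passed. Without control replicate 2, DNA replication genes were at -0.27, and androgen receptor repressed genes (0.40), steroid metabolism (0.47), the SOX family (-0.47) and unfolded protein response genes (0.32) passed, 10 lists in all. Under the replicate block androgen receptor repressed genes (0.38), steroid metabolism (0.46) and fibroblast and stromal markers (0.54, only 4 genes tested) passed. None of these lists passed at an estimated correlation in any of these fits (smallest camera adjusted p = 0.918).

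HMGN2P46 was the 1 gene called with each siRNA. In simulated unchanged groups that share the control arrays, 0.0700 higher genes per simulation were called with both, and at most 1, so an overlap of 1 did not exceed the simulated ones. Independent lists of 2 and 11 higher genes would share 0.00177, a value that leaves out the shared controls. Of the 12 lower genes of siRNA B, 0 were called with siRNA A, and 115 genes were called with both under the replicate block (16 with median centring added). Across the tested genes, which are not independent replicates, the log2 fold changes of the 2 siRNAs correlated at 0.54, against 0.50 (0.49 to 0.51) in simulated unchanged groups that share the control arrays, and 68.5% of genes had the same sign against 66.6% simulated. The 2 control arrays could not be split into 2 groups of 2, so part of the correlation and of the shared signs may come from the shared controls. The simulated groups share controls as well, and the cause of the excess over them was not tested. The covariance, to which shared controls add the same amount in the simulation, was 0.0758 against 0.0456 simulated, a difference of 0.0302. The simulation left out deviations shared by same-numbered arrays of the 2 siRNAs, which correlated at 0.63. It also gave every array the same spread. The 2 control arrays correlated at 0.988, those of siRNA A at 0.973 and those of siRNA B at 0.965. The simulated values may thus overstate what the shared controls add, and they do not settle how much of the agreement comes from them.

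Compared directly, siRNA A and siRNA B differed in 12 genes. DDC was higher with siRNA A, at 1417 ± 393 against 185 ± 32.2 (SD, n = 2 each), and COL14A1 at 84.5 ± 24.4 against 2.40 ± 1.70, a level near the floor of the array. MET, the hepatocyte growth factor receptor, was higher with siRNA B, at 185 ± 59.8 against 27.8 ± 3.18, as was IGFBP5, a binding protein of insulin-like growth factors, at 305 ± 64.7 against 60.7 ± 0.0707. The log2 differences, siRNA A minus siRNA B, were 2.82 for DDC (limma adjusted p = 0.00186), 2.43 for COL14A1 and -2.17 for MET (limma adjusted p = 0.00568 each). The count of 12, with 6 in each direction and 1023 genes at an unadjusted p below 0.05, was 4 and 0 without replicates 1 and 2 of siRNA A, 288 and 0 without replicates 1 and 2 of siRNA B and 55 without control replicate 1 or 2. It was 361 with the replicate block (250 with median centring added). It was 0 after quantile normalization, median centring or scaling to a common trimmed mean or without the filter, in limma with 1515, 1450, 1479 and 1371 genes at an unadjusted p below 0.05.

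Cell cycle genes were higher with siRNA A than with siRNA B. DNA replication and G1/S genes differed by 0.59, with 44 of 45 positive and 3 called when adjusted over the list alone (camera adjusted p = 1.71e-18; adjusted p = 0.985 with an estimated correlation), and mitosis and G2/M genes by 0.54, with all 49 positive (camera adjusted p = 1.32e-16; adjusted p = 0.985 with an estimated correlation). Relative to the control mean, DNA replication genes were at 0.18 and 0.13 in the siRNA A arrays and at -0.37 and -0.49 in the siRNA B arrays. Cholesterol genes were higher with siRNA B, by -0.49 as siRNA A minus siRNA B (camera adjusted p = 1.31e-06; adjusted p = 0.985 with an estimated correlation). Androgen receptor activated genes differed by 0.24 and ribosomal genes by 0.12 (camera adjusted p = 0.0178 and 0.0187; adjusted p = 0.985 with an estimated correlation for both).

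The cholesterol difference was -0.09 without replicate 1 of siRNA A, -0.89 without its replicate 2, -0.96 without replicate 1 of siRNA B and -0.02 without its replicate 2. The mitosis difference was 0.33 without replicate 2 of siRNA A, and androgen receptor activated genes lost their call without that array (0.21, camera adjusted p = 0.0502). The ribosomal difference was 0.10 without replicate 1 of siRNA A, 0.31 without replicate 1 of siRNA B and -0.07 without replicate 2 of siRNA B. With the replicate block ribosomal genes lost their call (camera adjusted p = 0.0515). Fibroblast and stromal markers, only 4 genes tested, passed with it (-0.74, camera adjusted p = 0.000552, and 0.952 with an estimated correlation). Hypoxia genes, at -0.0082 with all arrays, were at -0.46 without replicate 1 and 0.44 without replicate 2 of siRNA A and at 0.52 and -0.54 without those of siRNA B, each past the camera test, with adjusted p = 0.809 to 0.928 with an estimated correlation. NF-kappaB genes, at 0.06, passed without replicate 1 (-0.73) or 2 (0.84) of siRNA A and without replicate 2 of siRNA B (-0.44), and oxidative phosphorylation genes without replicate 1 of siRNA B (-0.21), none of them with an estimated correlation (smallest camera adjusted p = 0.809). The 5 lists became 8 without either array of siRNA A or without replicate 2 of siRNA B.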

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

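All tests here, of array scaling, of the remaining SOX9 level and of the control arrays, were chosen after the result had been seen. The genes and lists were singled out because the effects of the 2 siRNAs differed in a direct test, and the replicate 2 pattern was seen in the list levels of single arrays.

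The 12 genes that differed, as log2 signal with siRNA A minus siRNA B, were DDC (2.82), COL14A1 (2.43), SLC25A39 (1.79), SPCS3 (1.64, but -0.27 with the median over probe sets), RAB8B (1.64) and SMCO4 (1.55), higher with siRNA A, and MET (-2.17), IGFBP5 (-2.05), DIO1 (-2.03), CYP1B1 (-2.02), UGT2B15 (-1.78) and UGT2B28 (-1.56), higher with siRNA B. The largest limma adjusted p among them was 0.0464. The lists that differed were DNA replication and G1/S genes (0.59), mitosis and G2/M genes (0.54), androgen receptor activated genes (0.24), cytosolic ribosomal protein genes (0.12) and cholesterol and fatty acid synthesis genes (-0.49), with adjusted p = 0.985 with an estimated correlation for each.

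DNA replication and mitosis genes were lower with siRNA B than with siRNA A. Quantile normalization left their difference together at 0.56 (SE 0.03 over 94 members), against 0.56 as deposited. Both are relative to the mean of all tested genes, so an array-wide factor was already taken off and was not tested. The values argue only against differences in the distribution of signals between arrays. From replicate 1 to replicate 2 within each siRNA, mitosis genes changed by 0.37 (SE 0.04 over genes, which are not independent) where the SOX9 signal predicted -0.45, and net of the control arrays by 0.25 against -0.23, which argues against the remaining SOX9 level as the only cause for them. This takes the SOX9 signals as exact, though their difference between the siRNAs did not pass. A condition of the replicate 2 cultures could also hide a part played by the remaining SOX9 level. For DNA replication genes it cannot be told apart, since the change was -0.078 (SE 0.05) against -0.49 as measured but -0.41 (SE 0.06) against -0.25 net of control, and for both lists together it was 0.15 (SE 0.04) against -0.47 and -0.067 (SE 0.05) against -0.24. An effect of 1 siRNA on other transcripts stays open and was not tested.

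Genes of hypoxia, chemokines and cholesterol synthesis moved in replicate 2 of both SOX9 siRNAs more than in replicate 1. For hypoxia genes the difference between the replicates was -0.98 as deposited and -0.99 (SE 0.13 over 31 members) after quantile normalization. This too argues only against differences in the distribution of signals, since an array-wide factor was already taken off both values. If the remaining SOX9 level alone set the hypoxia and inflammatory genes, siRNA A would exceed siRNA B by 1.28, or by 2.13 net of the control arrays. This takes the SOX9 signals as exact. The difference was 0.015 (SE 0.06 over 49 members, which are not independent). For cholesterol genes it was -0.49 (SE 0.05) against a predicted -1.02, too near the bound of 50% to decide, though farther from the -2.06 predicted net of control. Over the 74 members, turned to the pattern's direction, the control arrays differed by 0.10 (SE 0.03 over members) against 1.01 in the SOX9 siRNAs. That is well short of what a condition acting alike on all replicate 2 cultures would give. Only 1 pair of control arrays bears on it, so such a condition cannot be told apart. The rule here was looser than the 50% bound used for SOX9. Only a control change in the opposite direction would have counted against a shared condition. No biological explanation beyond the SOX9 level was tested.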

How the results depend on the processing

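Scaling to a common trimmed mean, the block with median centring and the fits without either replicate of both SOX9 siRNAs were chosen after the data had been seen. Fold changes were steadier than calls. The prior degrees of freedom of limma were 12.9, and 4.08 after quantile normalization, 4.46 after median centring, 4.16 with a common trimmed mean and 6.00 without the filter, fits that each gave 0 genes in every comparison and 0 called by both siRNAs. The median log2 fold change of all genes moved by less than 0.1 between scalings. Dim genes are limited by signal: 39.1% to 43.8% of probe sets lay below a signal of 16.

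Counts of genes are in the order both siRNAs, siRNA A, siRNA B, siRNA A against siRNA B and called by both. An offset of 64 gave 9 and, by both, 0. The filter at the 70th percentile gave 9 for both siRNAs, 41 for siRNA B, 19 between the siRNAs and 2 by both. The median over probe sets gave 1 for siRNA A and 4 between the siRNAs. Probe sets in place of genes gave 1 for both siRNAs and 0 by both. Without the trend the counts were 1 for both siRNAs, 14 for siRNA B, 6 between the siRNAs and 0 by both, and with robust eBayes 36 for siRNA B and 25 between the siRNAs. An adjusted p below 0.01 gave 1, 1, 0, 4 and 0. Only the compared groups gave 8 for siRNA B, 57 between the siRNAs and 0 by both. The SOX9 siRNA arrays as 1 group gave 0. In that 1-group fit the count was 0 without replicate 2 of both SOX9 siRNAs, and 602 without replicate 1 of both. The cause was not tested for any of these counts, and a lower prior did not always go with fewer calls, since it was 8.45 without replicate 1 of siRNA B, with 62 genes for both siRNAs.

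With the replicate block the counts were 440, 224, 732, 361 and 115, and 5, 2, 23 and 12 of the calls made without it were shared; the SOX9 log2 fold change was -1.02 (limma adjusted p = 0.00184). Of the 136 genes open to naming for both siRNAs, 53 were called with the block and 5 without, and no named gene lost its call. Among lists it ended 1, 1, 0 and 1 calls and added 2, 2, 3 and 1 in the first 4 comparisons, and it changed no other call. The block with median centring gave 60, 23, 562, 250 and 16, and SOX9 at -0.98 (limma adjusted p = 0.0343). SOX9 was at -1.41 (limma adjusted p = 0.0116) without replicate 1 of both SOX9 siRNAs, with the siRNAs as 1 group. In that fit with all arrays it was at -1.02 (limma adjusted p = 0.815).

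Lists passed in these numbers: 0 in each comparison with an estimated correlation and with fry; 3 for both siRNAs without replicate 2 of both SOX9 siRNAs; 6 for siRNA A without the filter; 3 for siRNA B after quantile normalization and 10 with the median over probe sets. Beta-catenin/TCF targets no longer passed without the filter (-0.16), with an estimated correlation and with fry (-0.26 each) and without replicate 2 of both SOX9 siRNAs (-0.12). WNT antagonists passed with the median over probe sets (-0.18) and with the block and median centring (-0.16), with adjusted p of 0.946 and 0.757 with an estimated correlation. WNT ligands and receptors were at 0.0027 with the 70th percentile filter, and WNT signal transduction genes at 0.012 there and at 0.0082 without replicate 1 of both SOX9 siRNAs, none past the test.

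Among results for both siRNAs and between the siRNAs, the following values turned their direction with the test passed before or after. Turns in which neither passed are only counted, and those of lists for a single siRNA stand in the Results. SPCS3 between the siRNAs was -0.27 with the median over probe sets. For both siRNAs, DNA replication genes were at 0.027 without control replicate 2 and ran from -0.31 over the single arrays left out, hypoxia genes were at 0.065 without replicate 2 of both SOX9 siRNAs, and oxidative phosphorylation genes at -0.052 without siRNA B replicate 2 (highest 0.058) and -0.079 without replicate 2 of both SOX9 siRNAs. Between the siRNAs, NF-kappaB genes were at -0.73 without siRNA A replicate 1 and -0.44 without siRNA B replicate 2 (highest 0.84), hypoxia genes at 0.44 without siRNA A replicate 2 and 0.52 without siRNA B replicate 1 (lowest -0.54), and ribosomal genes at -0.072 without siRNA B replicate 2 (highest 0.31). The cause was not tested, beyond the fewer arrays.

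Leaving out 1 array at a time, where the lone array of a group is assumed to vary like the others, gave 0 to 62 genes for both siRNAs, 0 to 18 for siRNA A, 0 to 991 for siRNA B, 0 to 288 between the siRNAs and 0 to 11 by both. SOX9 ran from -1.23 to -0.81. Lists passed in numbers from 7 to 11, 3 to 10, 6 to 10 and 6 to 8 in the first 4 comparisons. The shift of beta-catenin/TCF targets ran from -0.35 to -0.18, of WNT ligands and receptors from -0.17 to -0.07, of WNT antagonists from -0.20 to -0.12 and of WNT signal transduction genes from -0.045 to 0.0047. Of the other results for named genes and lists, 4173 values kept their direction and side of the threshold, 278 no longer passed, 201 newly passed and 78 that passed neither way changed sign. The 4173 include results that passed in neither fit, and 5 of the 136 genes open to naming for both siRNAs were called at first. The tally thus says little about how firmly calls held.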

Other observations

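The test of the SOX9 signal against random orders was set before its random orders were seen, when the number of genes in the real order was already roughly known; the neighbouring genes and the genes shared by the replicates were looked at after their values had been seen, and the tests of orders within replicate numbers, of orders within groups and net of the control arrays were also chosen after the result had been seen.

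HMGN2P46, SLC30A4 and COXFA4L3, the 3 genes that rose with both siRNAs, lie next to each other: no other tested gene stands between them in the RefSeq gene table of GRCh38.p14, and SLC30A4 and HMGN2P46 overlap there, so their signals may not be separate. Their log2 fold changes were 1.95, 1.66 and 1.501. The 3 nearest tested genes on each side had values from -0.43 to 0.044, none past the test. HMGN2P46 kept its direction over the alternatives, from 1.43 to 2.23.

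The replicates were also compared without shared arrays, as the mean of the SOX9 siRNAs minus control within replicate 1 and within replicate 2. Of the 100 lowest genes of each, 15 were shared, and of the 100 highest 20, where chance gives 0.804 if every gene is equally likely to be extreme, which noisier genes are not. The SD over all genes was 0.29 in replicate 1 and 0.50 in replicate 2, so that values larger in replicate 2, as in 14 of the 15 and 17 of the 20, are expected. LUM, lumican, was at 1.41 and 1.62. FZD7 was at -1.28 and -2.28 and NPY6R at -1.66 and -2.76. Across genes, which are not independent, the correlation was 0.38.

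One hypothesis is that expression follows the remaining SOX9 signal of each array. A limma regression on that signal, SOX9 left out, called 1020 genes, 540 that fall with SOX9 and 480 that rise as it falls. Of 100 orders of the 6 signals, the real one included, 1 gave as many, and the highest of the others gave 313. These orders take the arrays as free of their replicate numbers, although SOX9 was lower in replicate 2 of all 3 groups. With the replicate block the regression called 817 genes, and of the 36 orders within replicate numbers, the real one included, 1 gave as many, with 589 in the highest other. Both kinds of order also break the groups, so neither count can favour the SOX9 signal over the group, and the group comparison with the block called 732 genes for siRNA B. Of the 8 orders in which only the replicates of a group change places, the real one included, 1 gave as many as 1020 and the highest other gave 745, too few orders to decide. The SOX9 signal and the group cannot be told apart here. The signal was measured on the same arrays, so any array condition that moves SOX9 and other genes together could give the same count.

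Over 7 relations tested with exact permutation of the 6 arrays, which ignores their replicate numbers, 2 passed after adjustment by Pearson and 0 by Spearman. The relations were picked from the 33 lists and the first principal component without being fixed beforehand, and the adjustment covered them alone. The permutations also break the groups, so a relation that passed cannot favour the SOX9 signal over the group. Cholesterol genes had Pearson r = -0.94 (exact p = 0.0125, adjusted 0.0438) and Spearman rho = -0.89 (exact p = 0.0333, adjusted 0.117), with r = -0.87 without the 2 arrays farthest from the median SOX9 signal. Beta-catenin/TCF targets had r = 0.85 (exact p = 0.0306, adjusted 0.0713) and rho = 0.83 (exact p = 0.0583, adjusted 0.136), and r = 0.45 without those 2 arrays, so that relation rests on them. The first principal component had r = -0.92 (exact p = 0.00972, adjusted 0.0438) and rho = -0.94 (exact p = 0.0167, adjusted 0.117), and r = -0.72 without those 2 arrays. The value of r was 0.76 for NF-kappaB genes (exact p = 0.0833), 0.73 for hypoxia genes (exact p = 0.126), 0.65 for DNA replication genes (exact p = 0.168) and -0.00074 for mitosis genes (exact p = 0.999). Without those 2 arrays these were 0.63, 0.31, 0.72 and 0.073. Tests on differences between the siRNAs and between replicates argue against the remaining SOX9 level as the only cause for hypoxia and inflammatory genes (0.015 against 1.28 predicted) and mitosis genes (0.37 against -0.45), as measured and net of the control arrays. They take the SOX9 signals as exact, and a condition of the replicate 2 cultures could hide a part played by SOX9. For DNA replication genes they leave the SOX9 level open.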
